A study of Mus musculus with 4 samples.

How the data were processed

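RNA of primary tail skin keratinocytes from mice with a floxed Prdm1 gene was measured on the Affymetrix Mouse Expression Array 430A, an array read by probe sets near the 3′ end of transcripts. Per the labels' protocols, total RNA was treated with DNase, and biotin-labelled cRNA was made with a 3′ in vitro transcription kit. The 4 samples are 4 groups of 1 array each, given by the labels: control cells (without CreER) and CKO cells (with CreER), each with ethanol or with 4-hydroxytamoxifen (4OHT) from day 1 to day 3, collected on day 5. By their source labels, control and CKO cells came from different mice, without and with CreER, so comparisons between genotypes also differ by animal. Whether the cultures of each genotype came from 1 or several mice is not given in the sources used here.

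The deposited table holds 1 intensity per probe set and array on a linear scale (22626 probe sets, 2.66 to 7167), which per the submitters' processing notes comes from RMA, a method that corrects the background, normalizes between arrays and summarises the probes of each probe set. The version of RMA and the form of its background model are not given in the sources used here. RMA pulls the arrays to similar distributions, so a shift of most transcripts in 1 culture would be lost, and it compresses differences of dim probe sets. The 4 arrays had medians between 19.95 and 20.22 and 25th percentiles between 7.11 and 7.48, and the table carries no detection calls, so it does not show which dim values are above background. Between 50 and 84 of the probe sets had identical values in any pair of arrays, and no pair of arrays was a copy. The Pearson correlation of log2 values over all probe sets was between 0.986 and 0.995.

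From these values log2 was taken, with no pseudocount and no further normalization. Gene names came from the platform annotation supplied with the data. Of the 22626 probe sets, 20380 named 1 gene, 691 named several and 1555 were not listed there. Entrez identifiers of 20351 matched the current gene table, and no symbol changed. A gene was represented by the probe set with the highest mean among those naming that gene alone (12393 genes), and 815 genes were represented by a probe set whose design allows cross-hybridisation (ending in _s_at or _x_at). A gene counted as measured when its highest value on the 4 arrays reached the median of the whole table (20.04 intensity units, 4.32 on the log2 scale), which left 7461 genes. For 33 named genes with a difference of at least 2-fold and a second measured probe set, each further probe set was set beside the main one in each such comparison. This gave 86 entries, in which 1 pair of probe sets can recur, and 2 of them, of Col4a1 and Igfbp4 against CKO EtOH, differed in sign. Sizes could differ with the same sign, as for Timp2 (1.09 and 0.17 against CKO EtOH).

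With 1 array per group there is no estimate of error, so no test was run and no p-value is given. A gene was counted in a comparison when the log2 difference was at least 1 (2-fold). A gene was called apart on an array when its log2 value lay at least 1 above the highest or below the lowest of the other 3 arrays, and the same count was made for each array as a yardstick. The comparisons were CKO 4OHT with CKO EtOH, CKO 4OHT with control 4OHT, control 4OHT with control EtOH, CKO EtOH with control EtOH, and the difference of the drug effects. Comparisons that share an array were set beside the same correlation with every other array in the shared place and beside the overlap of independent lists.

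The design, 29 gene lists, 9 lists of markers of other cells or of sex chromosome genes, the rule for named genes and the alternatives were fixed before the data were examined. A list was described when at least 5 of its members were measured, which held for 31 lists. Its median was placed among 10000 random lists of the same size drawn from 20 bins of mean level. The rule for named genes took Prdm1, the 12 highest and 12 lowest genes apart in CKO 4OHT, the 10 highest and 10 lowest in each comparison of CKO 4OHT, the 6 highest and 6 lowest in each other comparison, and list members that were apart or at least 2-fold different in a comparison. For a list with no such member it took the 2 with the highest mean level. Genes named beyond this rule (Sprr1a, Csf1, Jun, Lce3c, Krt14, Krt5, Cdt1, Mcm5, Gpnmb, Sox10 and genes given as the counterpart of a named one, the members of an overlap of comparisons, Dbp, Nfil3 and genes of the lists added later) were chosen after their values were seen. Gene symbols follow the annotation, where Il1f5, Il1f6, Il1f8 and Il1f9 are older names of the IL-36 family.

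The counting steps were tested on simulated data made from the arrays. For genes apart in CKO 4OHT and for CKO 4OHT against CKO EtOH, 100% of 100 genes set 3-fold and 100% of 100 genes set 8-fold apart were called in the right direction, and 0% of 7261 unshifted genes were called, with 7461 genes in the step. Of 100 simulated lists without a shift 5 lay outside the central 95% of random lists, and of 100 lists shifted by 0.5 on the log2 scale all 100 did. The noise was drawn independently for each gene, at the size seen between CKO EtOH and control EtOH, the most alike pair of arrays. The 95th percentile of the absolute difference was 0.42 in that pair, against 0.68 between the control arrays. These rates therefore check the counting and are not error rates of the real arrays.

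The alternatives were no level filter or a filter at the 75th percentile of the table, a 1.5-fold threshold, cyclic loess, quantile normalization or median centring of the arrays, the mean of all probe sets of a gene, leaving out _s_at and _x_at probe sets, counting probe sets, and taking the mean of the other 3 arrays or leaving each of them out. Cyclic loess and quantile normalization used limma 3.58.1 in R 4.3.3, and all other steps Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. Probe sets that name no gene or several were left out of the gene comparisons. Scanner files were not used here, and no genome coordinates were used.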

Results

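Transcript levels were measured in primary keratinocytes, the epithelial cells of the epidermis, that had been taken from the tail skin of C57BL/6 mice carrying a floxed Prdm1 gene. Prdm1 encodes Blimp-1, a zinc finger transcriptional repressor known from plasma cell differentiation and from the upper layers of the epidermis. A floxed gene is flanked by recognition sites of the Cre recombinase, so that Cre can cut part of it out. The cells called CKO here also carried CreER, a Cre recombinase fused to the ligand-binding domain of an estrogen receptor, which acts in the nucleus once 4-hydroxytamoxifen (4OHT) binds it. The cells called control had the floxed gene without CreER. Each genotype was given 4OHT or its solvent ethanol (EtOH) from day 1 to day 3 of culture and was collected on day 5, which makes 4 groups: control EtOH, control 4OHT, CKO EtOH and CKO 4OHT. By the labels, only the CKO 4OHT cells had both the recombinase and its inducer. Each group had 1 array, so there were no replicates, no difference could be tested, and 4 arrays limit the precision of every value below. Levels are RMA intensities on a linear scale, differences are on the log2 scale, and "higher" and "lower" in a count mean a difference of at least 2-fold between the arrays compared. The 4 arrays had medians between 19.95 and 20.22 intensity units, and 7461 named genes reached the median level of the table on at least 1 array.

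The targeted gene was examined first. Prdm1, read by a single probe set (1420425_at), had an intensity of 20.7 in control EtOH, 52.4 in control 4OHT, 17.0 in CKO EtOH and 6.43 in CKO 4OHT. The CKO 4OHT value was 2.64-fold below the nearest of the other 3 arrays and lay under the 25th percentile of its own array, 7.11, so the remaining level is not resolved from dim signal. Which part of the gene was floxed is not given in the sources used here, and a probe set outside the deleted part would not report the deletion directly. Prdm1 was also 1.34 log2 higher in control 4OHT than in control EtOH, in cells without CreER. The Esr1 probe set (1421244_at), which reads the estrogen receptor gene, had intensities of 54.3 and 44.4 in CKO EtOH and CKO 4OHT against 11.3 and 18.2 in control EtOH and control 4OHT. Prdm1 was thus lowest on the array labelled as the deleted culture, and Esr1 was higher on both arrays labelled as carrying CreER. Eif2s3y, a gene of the Y chromosome, was between 86.1 and 93.9 on the 4 arrays.

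**Figure D1:**
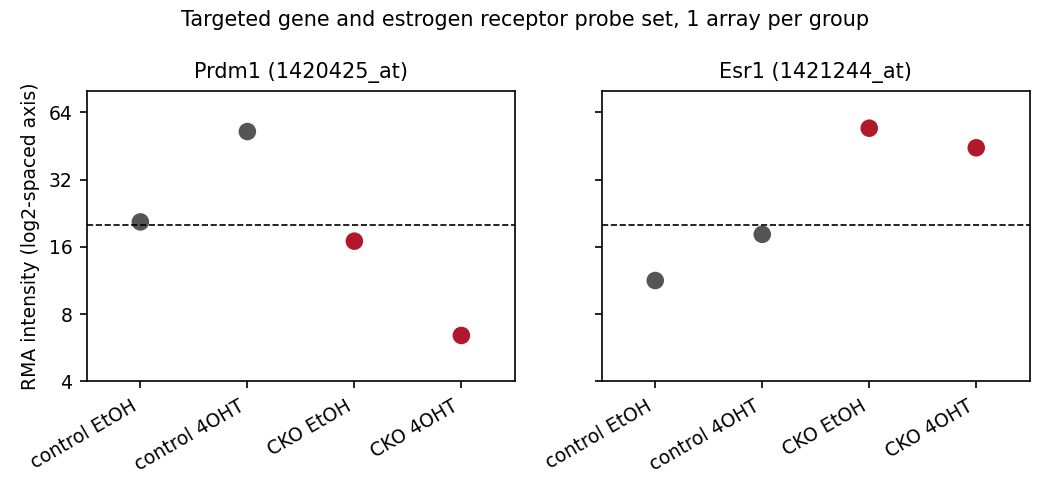
RMA intensity (log2-spaced axis) of the Prdm1 and Esr1 probe sets, 1 point per array, grey for control and red for CKO cells; the dashed line is the level filter of 20.04. Prdm1 was lowest in CKO 4OHT at 6.43, and Esr1 was higher on both CKO arrays (54.3 and 44.4) than on both control arrays (11.3 and 18.2).

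The central comparison asked which genes set the CKO 4OHT cells apart from all other cells. Cxcl2 and Il24 were the furthest above. Cxcl2, Cxcl1 and Cxcl5, chemokines that attract neutrophils, had intensities of 220, 591 and 121 in CKO 4OHT, 17.1-fold, 11.01-fold and 7.496-fold above the highest of the other 3 arrays. On those arrays Cxcl2 was at 9.06 to 12.9 and Cxcl5 at 9.87 to 16.1, under the level filter, so their folds and ranks are imprecise. Il24, a cytokine of the IL-10 family, reached 920, 17.1-fold above the next array. Hmga2, a chromatin protein typical of embryonic tissue, reached 356 (15.99-fold), and Fst, the activin antagonist follistatin, reached 569 (11.2-fold). Dusp6, a phosphatase that acts on ERK kinases, was 8.68-fold above the next array, Phlda1 8.42-fold, Fos, a subunit of the AP-1 transcription factor, 5.33-fold, and Ccn2, a matricellular growth factor, 4.04-fold. Ifi209 (5.08-fold) and Mal (4.49-fold) completed the 12 highest genes.

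Rptn was the furthest below. It encodes the cornified envelope protein repetin and had an intensity of 3.82 in CKO 4OHT against 53.4 to 178 on the other arrays, 14.0-fold below the nearest of them. Krt1, the keratin of the first suprabasal layers, was 21.8 against 136 to 246 (6.24-fold). Lce1d and Lce1f, late cornified envelope proteins, were 5.98-fold and 5.26-fold below the nearest array. Other genes among the 12 lowest were Matn2, an extracellular matrix protein (6.45-fold), Chdh, choline dehydrogenase (6.27-fold), Lgals9, the lectin galectin-9 (4.58-fold), Vav3, a guanine nucleotide exchange factor (4.32-fold), Igfbp3, an insulin-like growth factor binding protein (3.99-fold, 99.9 against 399 to 797), Fgf13 (3.86-fold), Col4a1, a basement membrane collagen (3.53-fold), and Fxyd6 (3.48-fold). A second Col4a1 probe set (1426348_at) did not share the difference and was at 30.7 in CKO 4OHT and 30.4 in CKO EtOH.

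In all, 56 genes lay at least 2-fold above and 81 at least 2-fold below every other array in CKO 4OHT. The same count gave 21 and 2 genes for control 4OHT, and 0 and 0 for both control EtOH and CKO EtOH. The count of genes above every other array became 100 when control 4OHT was left out of the comparison. Levels under about 10 are close to the floor of these arrays, so folds that rest on such a value, as for Rptn and Lce1d, are imprecise. So are the values of Cxcl2 and Dusp6 against control 4OHT, where their levels were 9.94 and 9.75, and the order of the highest genes there.

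**Figure D2:**
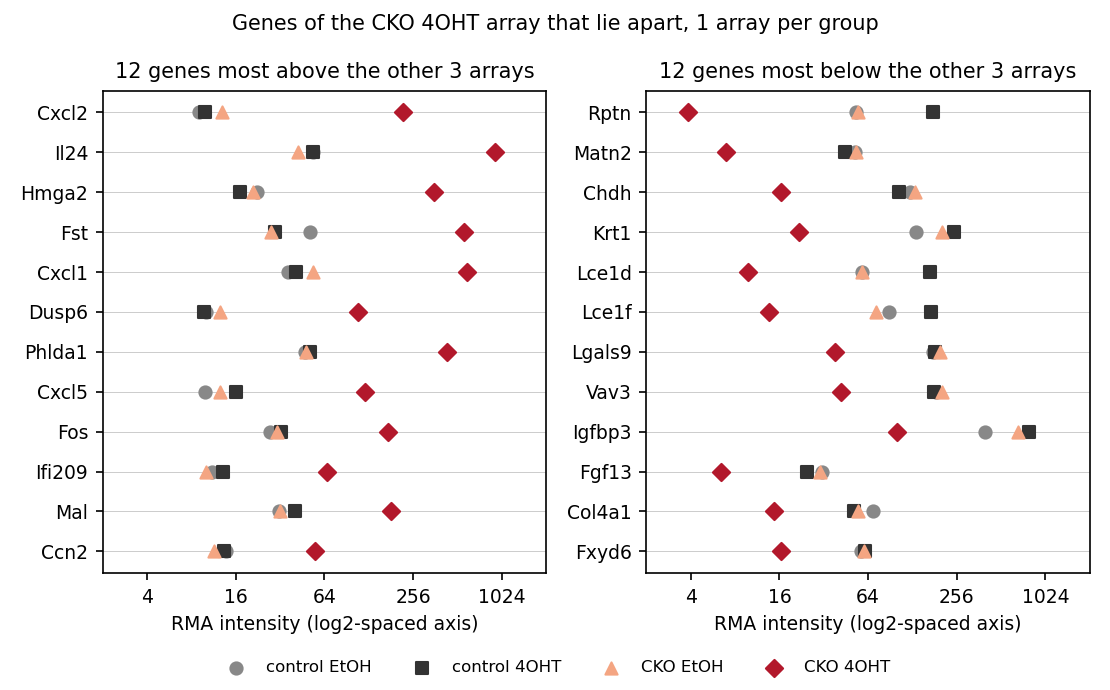
RMA intensity (log2-spaced axis) of the 12 genes furthest above and the 12 furthest below the other 3 arrays in CKO 4OHT, 1 point per array. In each row the red diamond (CKO 4OHT) stands apart, from 17.1-fold for Cxcl2 to 4.04-fold for Ccn2 on the left and from 14.0-fold for Rptn to 3.48-fold for Fxyd6 on the right.

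Gene lists fixed before the data were examined showed how these genes group. Of 30 measured suprabasal and cornified envelope genes, 10 lay apart in CKO 4OHT, all of them lower. These were Rptn, Krt1, Hrnr (hornerin, 10.5 against 28.2 to 89.6) and 7 of the 9 measured Lce genes, which are Lce1a2, Lce1b, Lce1d, Lce1f, Lce1h, Lce1i and Lce3a. None of the 8 measured Sprr genes, which encode small proline-rich cornified envelope proteins, lay apart. Sprr1a was 5075 in CKO 4OHT against 3131 in CKO EtOH and 4725 in control 4OHT. Probe sets of the Lce, Sprr and Saa families can share sequence between near-identical genes, so single members of these families are less certain than the group.

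Of 5 measured neutrophil-attracting chemokines and granulocyte growth factors, 4 lay apart and higher (Cxcl1, Cxcl2, Cxcl5 and Lif, the leukemia inhibitory factor, at 71.2 against 22.3 to 25.2), while Csf1 did not (32.2 against 26.8 to 35.5). Cxcl2 and Cxcl5 reached the level filter in CKO 4OHT alone. The 5 members under the filter were no higher than 7.79 on any array, and with them the medians of the 10 genes were 0.19 against CKO EtOH and 0.37 against control 4OHT. Among 10 AP-1 transcription factors, Fos (172 against 27.1 to 32.3) and Fosl1 (59.4 against 17.1 to 17.5) lay apart and higher, and Jun, at 147, was below the other arrays by less than 2-fold. Hbegf, a ligand of the EGF receptor, was 233 against 52.6 to 67.1, and it was the single gene apart in both the EGF family list (8 measured) and the wound-activated keratinocyte list (12 measured). Tnfaip2, at 131 against 39.7 to 44.4, was the 1 gene apart among 15 NF-kB regulators and targets.

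The comparison of CKO 4OHT with CKO EtOH set inducer against solvent in cells with CreER. It had 133 genes higher and 139 lower. The 10 highest were Il24 (4.44), Fst (4.35), Cxcl2 (4.10), Hmga2 (4.08), Cxcl1 (3.46), Cxcl5 (3.27), Phlda1 (3.16), Dusp6 (3.12), Cst6 (2.98), the epidermal cysteine protease inhibitor cystatin M/E, and Ifi209 (2.72). The 10 lowest were Rptn (-3.83), Krt1 (-3.23), Chdh (-3.02), Matn2 (-2.93), Igfbp3 (-2.75), Saa3 (-2.70), an acute phase protein, Lce1d (-2.58), Lce1f (-2.40), Lgals9 (-2.37) and Vav3 (-2.30). Because CreER was present on both sides, this comparison contains the effect of the drug itself as well as that of Cre activity.

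Cornified envelope genes did not move as 1 block here. Of the 30 members, 11 were lower, 2 were higher and 17 were neither, with a median difference of -0.40. The higher members were Tgm1 (1.56), the transglutaminase that crosslinks the envelope, and Klk7 (1.01), a protease of the cornified layer. Of 14 epidermal lipid barrier genes, 3 were higher and none was lower, with a median of 0.58. These were Alox12b (1.64), a lipoxygenase of barrier ceramides, Degs2 (1.23), a ceramide desaturase, and Ugcg (1.20), which makes glucosylceramide. Of 13 antimicrobial and alarmin genes, 2 were higher, Defb4 (1.73) and Defb3 (1.72), both beta-defensins, and 5 were lower, Saa3 (-2.70), Saa1 (-1.87), Wfdc12 (-1.67), Lpo (-1.28) and Lcn2 (-1.09), with a median of -0.41.

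The EGF family list had a median of 0.94, with 4 of 8 members higher: Hbegf (1.81), Epgn (1.28), Tgfa (1.20) and Ereg (1.06), all of them ligands. Of 15 extracellular proteases and inhibitors, 5 were higher, Klk6 (1.91), Klk8 (1.77), Mmp3 (1.15), Klk10 (1.13) and Timp2 (1.09, and 0.17 to 0.72 by its other measured probe sets), and 2 were lower, Mmp2 (-1.30) and Adamts1 (-1.09), with a median of 0.54 that was -0.055 without the level filter. The AP-1 list had a median of 0.46. Of 8 sebocyte genes, Cidea (1.08) was higher and Mgst1 (-1.56) lower around a median of 0.60. In the p53 target and cell cycle inhibitor list, 2 of 21 members were higher, Plk2 (1.01) and Mdm2 (1.01), around a median of 0.32.

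Interferon-stimulated genes had a median of -0.55, with Psmb8 (-1.57), an immunoproteasome subunit, and Irf1 (-1.13) lower among 11 members. The median of this list was 0.11 when only brighter genes, 4 of them, were kept. Among 34 cell cycle genes the median was -0.25. Mki67 (-1.02), a marker of proliferating cells, was lower, whereas Ccnd1 (1.28), cyclin D1, and Tk1 (1.13), thymidine kinase, were higher. Of 18 hypoxia and glycolysis genes, Slc2a1 (-1.25), Aldoc (-1.19) and Bnip3 (-1.12) were lower and none was higher, with a median of -0.20. Lfng (-1.45) was the 1 lower gene among 8 Notch pathway genes (median -0.33). The unfolded protein and amino acid stress list had no member past 2-fold (22 measured, median -0.18), and its brightest genes Asns and Hspa5 differed by -0.59 and 0.20.

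The comparison of CKO 4OHT with control 4OHT set CreER against no CreER, with the drug on both sides. It had 108 genes higher and 167 lower. Cxcl2 (4.47), Hmga2 (4.37), Fst (4.27), Il24 (4.10), Cxcl1 (3.86), Dusp6 (3.47), Phlda1 (3.07) and Cxcl5 (2.91) again led the higher genes, followed by Odc1 (2.57), the first enzyme of polyamine synthesis, and Procr (2.45), the endothelial protein C receptor. The 10 lowest were Rptn (-5.54), Rnase2b (-4.22), Lce1d (-4.11), Lce1f (-3.65), Krt1 (-3.50), Lce1a2 (-3.11), Hrnr (-3.10), Prdm1 (-3.03), Igfbp3 (-3.00) and Saa3 (-2.97).

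The cornified envelope list stood lower in this comparison than in the previous one, with 17 of 30 members lower, none higher and a median of -1.06. All 9 measured Lce genes were lower on the log2 scale, 8 of them past 2-fold, from -2.04 for Lce1a1 to -4.11 for Lce1d, and Lce3c differed by -0.73. Of the 8 Sprr genes, 5 were lower past 2-fold, led by Sprr2f (-2.58) and Sprr2k (-1.52), and Sprr1a was at 0.10. Tgm1 (0.14) and Klk7 (0.25) were near the drug-treated control. Among 13 antimicrobial genes, 7 were lower and none higher, with a median of -1.40; Defb6 (-2.06) and Lcn2 (-1.65), the iron-binding protein lipocalin-2, were among them. Dsc1 (-1.41), a desmosomal cadherin of the upper layers, was the 1 lower gene among 14 desmosome and tight junction genes, whose median was -0.30. The lipid barrier list had no member past 2-fold and a median of 0.14.

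Epithelial cytokines split in both directions. Of 12 members, Il24 (4.10), Tslp (1.43), a lymphopoietin of barrier epithelia, and Il1a (1.34) were higher. Il33 (-1.73), Il18 (-1.54), Il1f5 (-1.49), the IL-36 receptor antagonist, and Il1rn (-1.29), the IL-1 receptor antagonist, were lower. A second measured Il1f5 probe set differed by -0.51. The list's median was -0.59 and its mean 0.01, so the centre of this list has no clear sign; against CKO EtOH its median was 0.37, and -0.55 when only brighter genes were kept. Il1a at 36.9 and Il24 at 920 were the members apart in CKO 4OHT.

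Ccnd1 (1.75), Tk1 (1.25), Mdm2 (1.25), Gadd45a (1.36) and Hbegf (2.15) were higher than in control 4OHT. The p53 target list had a median of 0.44 and the EGF family list one of 0.55, but the latter was -0.17 without the level filter. Of 6 measured genes known as Blimp-1 targets in lymphoid or other cells, Fosl1 (1.78) and Myc (1.22) were higher, with a median of 0.57 that became -0.01 without the level filter. Basal keratinocyte genes had a median of -0.05 over 14 members. Krt14 and Krt5, the basal keratins, differed by -0.05 and -0.07, while Itga3 (1.37), an integrin of the basal surface, and Cd44 (1.27), a hyaluronan receptor, were higher. Of 11 interferon-stimulated genes, Psmb8 (-1.85), Irf1 (-1.21) and Ifih1 (-1.06) were lower, with a median of -0.33 (0.12 for the 4 brighter genes). Of the hypoxia and glycolysis genes, Aldoc (-1.87), Bnip3 (-1.31) and Pfkp (-1.03) were lower around a median of -0.29.

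Both comparisons of CKO 4OHT shared 73 higher and 110 lower genes, where independent lists of these sizes would share 1.93 and 3.11. Across genes the correlation of the log2 differences was 0.83 (Pearson) and 0.74 (Spearman), with a covariance of 0.169. Both comparisons use the CKO 4OHT array, which by itself creates such a relation. With control EtOH in that shared place and CKO 4OHT left out, the Pearson correlation was 0.63, with a covariance of 0.0453. It was 0.39 for control 4OHT and 0.19 for CKO EtOH, with covariances of 0.0492 and 0.0227. Those last values still use CKO 4OHT as a compared array, so they depend on the first result and are no separate yardstick. Part of the overlap may come from the shared array, and genes are not independent replicates.

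The drug without CreER was read from control 4OHT against control EtOH, a comparison that also holds any other difference between these cultures. It had 95 genes higher and 18 lower. The highest were Defb6 (2.58) and Defb3 (2.29), beta-defensins, Rnase2b (2.56), a secreted ribonuclease, Atp12a (1.95), a proton pump, Dsc1 (1.86) and Serpinb11 (1.75). The lowest were Kcnj15 (-1.29), Pola1 (-1.26), a DNA polymerase subunit, Zscan21 (-1.26), Phip (-1.24), Hells (-1.23), a chromatin remodeller of dividing cells, and Tmem184c (-1.15); other probe sets of Zscan21 differed by -0.30 and -0.44. At a 1.5-fold threshold the counts were 295 higher and 292 lower, so the excess of higher genes belongs to the large differences.

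Of 30 cornified envelope genes, 18 were higher with the drug in control cells and none was lower (median 1.05), among them Rptn (1.74), Sprr2i (1.69), Sprr2f (1.67), Tgm1 (1.51), Hrnr (1.51) and Cdsn (1.47), the adhesion protein corneodesmosin. Antimicrobial genes had 9 of 13 members higher, with a median of 1.30, including S100a9 (1.23), the alarmin subunit that reached 4308 intensity units. Epithelial cytokines had 5 of 12 higher (median 0.86), among them Il1f5 (1.46, and 0.41 by its second measured probe set), Il1f6 (1.35) and Il1rn (1.32). Lipid barrier genes had 4 of 14 higher (median 0.45) and desmosome and tight junction genes 2 of 14, Dsc1 and Cldn4 (1.25), with a median of 0.45. The cell cycle list had a median of -0.30 with no member past 2-fold. Tk1 (-0.99), Cdt1 (-0.98) and Mcm5 (-0.98), all of DNA replication, were among the lowest members.

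Genotype without the drug was read from CKO EtOH against control EtOH, which by the labels came from different mice. This comparison shares the control EtOH array with the drug comparison in control cells. The log2 differences of these comparisons correlated at 0.63 (Pearson). Only 4 genes were higher and none was lower: Esr1 (2.26), Saa3 (1.44), Saa1 (1.41) and Wfdc18 (1.05), a whey acidic protein family member. The next in order were Defb6 (0.93) and Wfdc12 (0.87). The lowest were Foxo3 (-0.93), Wtap (-0.90), Tk1 (-0.87), Fst (-0.87), Zscan21 (-0.84) and Chek1 (-0.81). Other measured probe sets of Foxo3 (-0.11), Wtap (0.02) and Zscan21 (-0.08 and -0.57) differed less. By their main probe sets, all genes named here differed in the same direction between control 4OHT and control EtOH. Examples are Saa3 (1.71), Saa1 (1.72), Wfdc18 (1.59), Wtap (-0.85) and Foxo3 (-0.73), while Esr1 differed less there (0.69) than here. Apart from Esr1, these differences may belong to the shared control EtOH array and cannot be assigned to genotype. Antimicrobial genes had 2 of 13 members higher and a median of 0.49, the cornified envelope list had a median of 0.11 with none past 2-fold, and the cell cycle list had a median of -0.18. The 95th percentile of the absolute difference over genes was 0.42 between these arrays, against 0.68 between the 2 control arrays and 0.87 in both comparisons of CKO 4OHT.

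The drug effect in CKO minus that in control asked what 4OHT did that depended on CreER. Of the measured genes, 205 were higher and 216 lower in this difference. The highest were Fst (5.13), Hmga2 (4.45), Il24 (4.45), Cxcl2 (3.96), Cxcl1 (3.29) and Odc1 (3.17), and the lowest were Rptn (-5.57), Saa3 (-4.41), Lce1d (-4.11), Krt1 (-4.09), Rnase2b (-3.82) and Igfbp3 (-3.75). The cornified envelope list had 18 of 30 members lower and none higher (median -1.29), and the antimicrobial list 9 of 13 lower (median -1.55). Some 24 genes were higher with 4OHT in both genotypes, where independent lists would share 1.69, and they included Tgm1, Alox12b, Klk6, Klk7, Klk8, Defb3, Defb4, Cst6, Cldn4 and Atp12a. This difference combines the values of 4 arrays, so it holds the error of all 4 as well as opposite drug differences added together.

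**Figure D3:**
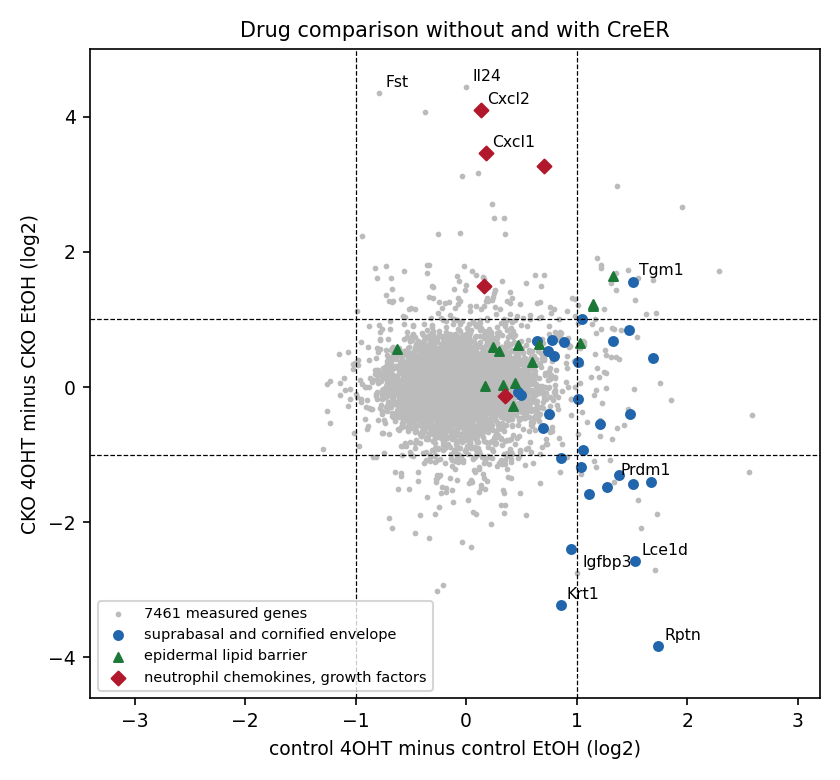
Log2 difference between 4OHT and EtOH in control cells (horizontal axis) against that in CKO cells (vertical axis), 1 point per measured gene (7461); dashed lines mark 2-fold. Cornified envelope genes lie to the right, with Rptn (1.74 and -3.83) lowest and Tgm1 (1.51 and 1.56) high on both axes, and Cxcl1 and Cxcl2 lie at the top near 0 on the horizontal axis.

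Lists of markers of other cells that a skin culture could hold were also read. Of 5 measured fibroblast genes, Col5a2 was apart and lower (10.7 against 23.01 to 29.98), with a list median of -0.32 against CKO EtOH and -0.38 against control 4OHT. Melanocyte genes (6 measured) had medians of 0.27 and 0.16 with none past 2-fold, the brightest being Gpnmb (95.4 in CKO 4OHT) and Sox10 (31.3). Of the leukocyte markers 4 were measured, and Cd68 was 98.2 in CKO 4OHT against 171 to 198 on the other arrays. Krt18, a keratin of simple epithelia and Merkel cells, was apart and higher (30.2 against 10.7 to 13.5), while its partner Krt8 was 43.8 against 73.4 to 90.2. Markers of endothelium (3 measured; Egfl7 at 77.2 and Eng at 46.4 in CKO 4OHT), muscle (2; Tnni2 at 29.7 and Mb at 16.8), fat (2; Lpl at 133 and Retn at 18.3) and Schwann cells or neurons (4; Mbp at 130 and Sox10) had no member past 2-fold.

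The remaining lists are given for both comparisons. For CKO 4OHT against CKO EtOH and against control 4OHT in turn, the medians were 0.07 and -0.03 for 17 xenobiotic and oxidative stress response genes, with Cyp1b1, Mgst1, Gsta3 and Gstm1 apart and lower and Gsta4 (1.32 and 1.08) higher in both. Another measured probe set of Gstm1 differed by -0.47 and -0.61. Aldh1a3 (1.67) and Hmox1 (1.54), heme oxygenase 1, were higher against CKO EtOH. The medians were -0.07 and -0.21 for 25 epidermal transcription factors, with Gata3 (-1.07 and -1.01) and Prdm1 apart and lower. Hopx (1.15 against CKO EtOH) and Myc (1.22 against control 4OHT) were higher. The medians were 0.05 and 0.14 for 12 hair follicle genes (Tbx1 and Gata3 apart and lower, Krt75 1.05 higher against CKO EtOH). The medians were -0.02 and -0.06 for 9 Wnt pathway genes (Fzd6, -1.38 and -1.11), and 0.10 and -0.14 for 7 other chemokines (Cxcl14, -1.41 and -1.07). They were -0.05 and -0.08 for 19 cholesterol biosynthesis genes (Dhcr7, 1.24 and 1.16, higher), and -0.29 and -0.29 for 9 estrogen receptor genes and targets (Igfbp4, -1.95 and -1.25, though another of its probe sets differed by 0.01 and -0.41). No member passed 2-fold among 14 heat shock genes (-0.06 and 0.02; Hspb1 at 0.02 and -0.04, Hspa8 at 0.55 and 0.57) or 7 antigen presentation genes (-0.07 and -0.28; H2-D1 at -0.17 and -0.28, H2-K1 at -0.19 and -0.33). The medians were 0.14 and 0.15 for wound-activated and -0.02 and -0.05 for NF-kB genes, and the second median of sebocyte, AP-1 and protease genes was -0.06, 0.06 and 0.05. For cell cycle, Notch and stress genes it was -0.08, -0.23 and -0.06.

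Each list median was also placed among 10000 random lists of the same size and level. Of 31 lists, 9 lay above and 9 below the central 95% of random lists in CKO 4OHT against CKO EtOH, and 4 above and 9 below in CKO 4OHT against control 4OHT, where 0.775 on each side is the number that random lists would give. The counts were 12 above and 1 below for the drug in control cells and 10 above and 1 below for genotype in ethanol, a comparison in which 4 genes passed 2-fold. Members of a list can vary together between any pair of cultures, so these positions describe the 4 arrays and are no test of treatment or genotype.

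**Figure D4:**
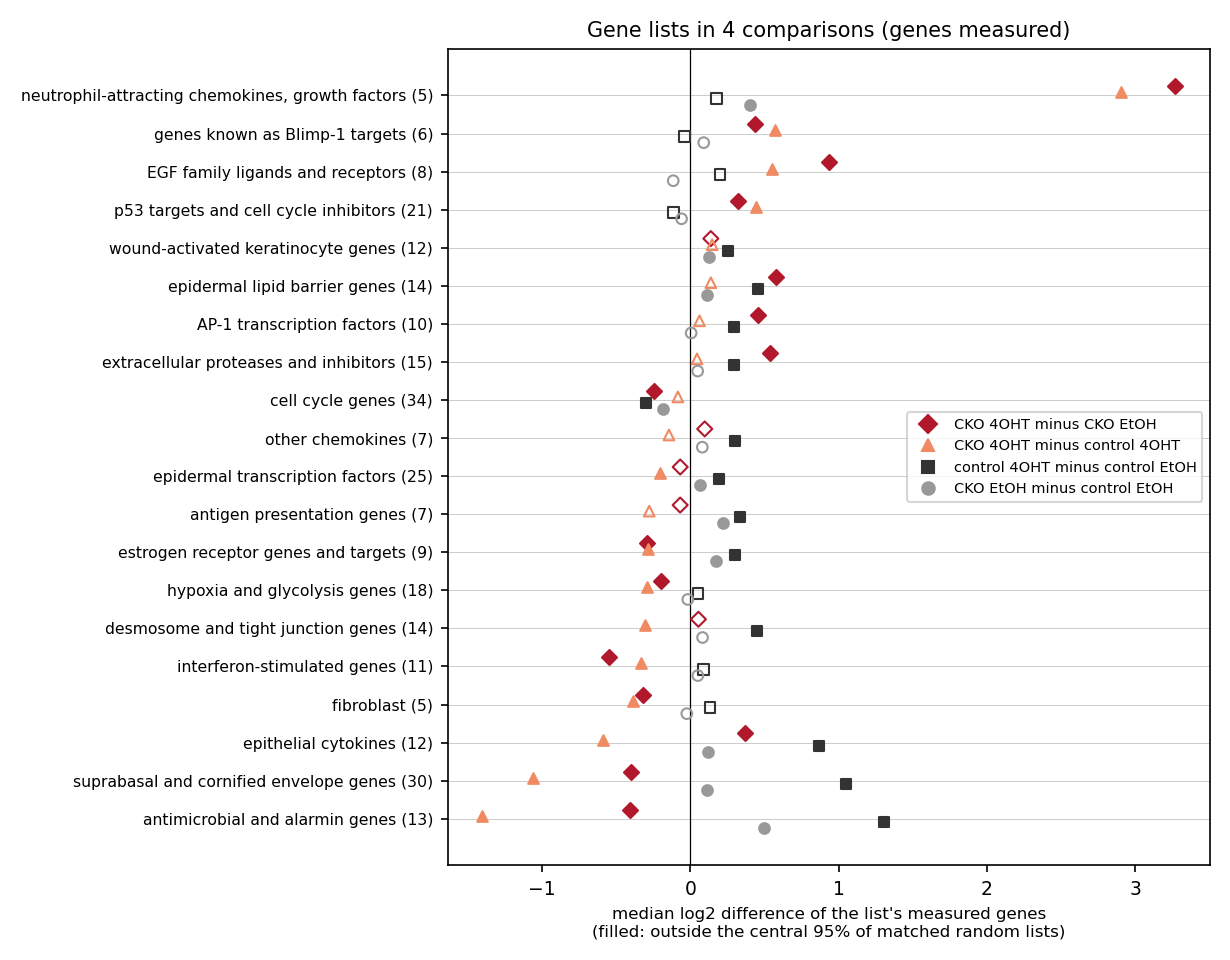
Median log2 difference of each gene list (number of measured genes in brackets) in 4 comparisons; filled symbols lie outside the central 95% of matched random lists, and lists are shown where this held in both comparisons of CKO 4OHT or in control 4OHT against control EtOH. The chemokine list, of which Cxcl2 and Cxcl5 reach the level filter in CKO 4OHT alone, is at 3.27 and 2.91 in the comparisons of CKO 4OHT (0.19 and 0.37 without the filter), and the cornified envelope list at -0.40 and -1.06 there and at 1.05 for the drug in control cells.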

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

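All tests in this part were chosen after the results they concern were seen, except the one on an intensity-dependent trend. Several results went one way with 4OHT in control cells and the other way in CKO cells. The cornified envelope list had a median drug difference of 1.05 in control and -0.40 in CKO, the antimicrobial list 1.30 and -0.41, and the estrogen receptor list 0.30 and -0.29. The last list holds Esr1, which was higher on both CKO arrays, and its median of -0.29 in CKO is the value of Esr1 itself. With 1 array per group these differences between the genotypes were not tested. Some 20 genes were at least 2-fold higher with the drug in control and at least 2-fold lower in CKO, where independent lists would share 1.77. No gene did the reverse, where independent lists would share only 0.32. The 20 genes were Prdm1 itself, Rptn, Hrnr, Lce1a2, Lce1b, Lce1d, Lce1h, Lce1i, Sprr2f, Saa1, Saa3, Lcn2, Lpo, Wfdc12, Wfdc18, Orm1, Rnase2b, Igfbp3, Aldoc and Blnk. The gene comparisons left out 927 measured probe sets that name no gene or several. Of these, 6 lay above and 9 below every other array in CKO 4OHT, and none did so for the other 3 arrays.

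The first pattern weighed was the higher level of cornified envelope and antimicrobial genes in control 4OHT, where no CreER was present. A trend of the difference with intensity does not account for it, since after cyclic loess the medians of the lists were 1.09 and 1.35. A drug effect that needs no CreER could be the cause, and so could a control 4OHT culture that had by chance differentiated further. For the first, the drug comparison in CKO had medians no higher than -0.40, but there the drug and the deletion cannot be told apart. Tgm1, Klk7, Defb3 and Defb4 of these lists were among 24 genes 2-fold higher with the drug in both genotypes, where independent lists would share 1.69. Against these stand the 20 genes that were higher in control and lower in CKO. For the second, the drug-free CKO EtOH culture also lay above control EtOH, by 0.11 for the cornified envelope and 0.49 for the antimicrobial list. The pattern and this check both subtract the same control EtOH array, so low values on it would raise both, and the check cannot decide. These arrays also differ in genotype, 0.11 is far below 1.05, and chance variation between cultures was not measured. With 1 culture per group both stay open, and the lower values of CKO 4OHT against control 4OHT contain this shift.

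The second pattern was the set of genes apart in CKO 4OHT, for which the design offers loss of Blimp-1 as the biological explanation. A loss of differentiated cells as a whole was weighed by the lipid barrier list. Its median of 0.58 against CKO EtOH (SD of its members 0.53) contains any effect of the drug. The list's median was 0.45 in control 4OHT against control EtOH. Against control 4OHT the median was 0.14 (SD 0.33), at percentile 87 of random lists. The cornified envelope list was at -0.40 and -1.06 in these comparisons, so the lipid barrier genes did not fall with it. The desmosome and tight junction list was at 0.055 and -0.30, the latter at percentile 0.18. The lists thus differ, a partial loss was not tested, and a loss of differentiated cells stays open. Leukocytes in that culture cannot be excluded as a source of the chemokines: the median difference of 21 leukocyte markers was no higher than 0.027 in both comparisons and none was 2-fold higher in both, but only 4 of them reached the level filter, and differences near the floor are compressed. A p53 response to Cre activity stays a candidate explanation for part of the set, since the p53 list lay at or above percentile 99.97 of random lists in both comparisons and Cdkn1a, a p53 target, was 0.61 higher in each. Cre activity and loss of Blimp-1 occur in the same array, and cells with CreER but without a floxed gene were not analysed here.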

How the results depend on the processing

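Of the alternative values of gene counts, of the correlation and of Prdm1, 112 were close to the reported ones. A further 27 counts moved by more than 1.5 times. For list medians the numbers were 918 close, 152 moved and 10 of opposite sign. For named genes they were 2613 close, 79 moved and none of opposite sign. Opposite sign was counted only for lists outside the central range of random lists and for named gene differences of at least 2-fold. Sign changes of other medians and differences were counted as close or moved. Cyclic loess kept 53 of the 56 higher and 79 of the 81 lower genes apart in CKO 4OHT, the mean of all probe sets kept 44 and 57, and leaving out _s_at and _x_at probe sets kept 54 and 72. With the filter at the 75th percentile fewer genes were tested: 37 higher and 48 lower were apart, 82 were lower against CKO EtOH, 64 higher and 107 lower against control 4OHT, 8 lower with the drug in control, 2 higher by genotype and 115 higher in the difference of drug effects. Counting probe sets, of which more were tested, gave 93 higher apart, 184 higher against control 4OHT, 43 lower with the drug in control and 346 higher in the difference. The 1.5-fold threshold gave by construction 185 and 238 apart, 423 and 408 against CKO EtOH, 496 and 451 against control 4OHT, 295 and 292 with the drug in control, 44 and 56 by genotype, and 830 and 635 in the difference (higher and lower). Against the mean of the other 3 arrays 113 and 127 genes were apart. Leaving out each other array in turn gave 61 to 100 higher and 84 to 110 lower, the 100 without control 4OHT.

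Among lists that lay outside the central range of random lists, medians changed sign only under the level filters. Without a filter, they were 0.033 for sebocyte genes and -0.063 for EGF family genes in the difference of drug effects, -0.17 for EGF family and -0.0088 for Blimp-1 target genes against control 4OHT, -0.055 for proteases against CKO EtOH and -0.00035 for epithelial cytokines by genotype. With the 75th percentile, epithelial cytokines were -0.55 against CKO EtOH, and interferon-stimulated genes 0.11, 0.12 and 0.0076 against CKO EtOH, against control 4OHT and in the difference. The cause was not tested beyond the change in which members were kept. Signal near background limits dim genes, and no paired analysis was possible because each group has 1 array.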

Other observations

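The tests on ERK and YAP below were chosen after values of some of their genes had been seen. Dusp6, Phlda1, Fos, Fosl1 and Hbegf, all induced by ERK signalling in other cells, lay apart and higher in CKO 4OHT. Other known targets of ERK signalling went both ways. Spry1, a feedback inhibitor of receptor tyrosine kinases, Etv4, an ETS transcription factor, and Epha2, an ephrin receptor, were 1.28, 1.32 and 1.51 log2 above CKO EtOH. Ets2 was lower in both comparisons of CKO 4OHT (-1.14 and -1.29), as were Egr1 (-0.91 and -1.01), Egr3 (-0.38 and -0.26), Epha4 (-0.26 and -0.71) and Srf (-0.26 and -0.50).

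Raised ERK signalling may accompany the higher Dusp6, Phlda1, Fos, Fosl1 and Hbegf. A list of other ERK feedback and immediate target genes, written without these 5, had 18 measured members and medians of 0.79 against CKO EtOH and 0.58 against control 4OHT, both at percentile 100 of random lists. For the drug in control cells, without CreER, its median was 0.16, at percentile 99.16. Of the 18, 11 were above 0 in both comparisons, 5 below 0 in both and 2 differed in sign; Spry1, Etv4, Epha2 and Lif were 2-fold higher in both and Ets2 2-fold lower, so the list did not move as a whole. Values of Lif and Dusp2 had been seen when the list was written, and the 16 other members had medians of 0.69 and 0.58. Higher Hbegf, loss of Blimp-1 and Cre activity all coincide with it in this design, and no protein measurement was used here.

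Raised YAP activity was considered because Ccn2, a YAP target, was apart and higher. The other 14 measured YAP and TEAD targets could not settle it: their median lay at percentile 53.2 against control 4OHT and 86.1 against CKO EtOH, with Igfbp3 lower and Fjx1 (1.02 above control 4OHT) higher. In comparisons without an expected deletion their median lay higher among random lists. It was 0.23 (percentile 99.81) for the drug in control cells and 0.18 (percentile 99.97) for genotype in ethanol. Both of these comparisons subtract the control EtOH array, so they are not independent observations. In the difference of the drug effects the median was -0.15 (percentile 6.37). A different clock time at harvest was considered because Dbp and Nfil3, both tied to the circadian clock, were apart and lower. The mean absolute difference of 10 other clock genes, 9 of them below 0 in both comparisons, lay at percentile 64.1 and 70.1 of random lists, so this too stays open.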
